A study of Mus musculus with 23 samples.

How the data were processed

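CUT&Tag was carried out on CD4 naive T cells from spleen and lymph nodes (labelled pLN) of WT and DDX55 knockout mice, with antibodies against H3K9me3, RNA polymerase II, DNA-RNA hybrids (S9.6), DDX55 and an HA tag, and with IgG. Per the labels, the hybrid controls received 20 U of RNase H, libraries of 200 to 1000 bp were selected, and reads were paired, 150 nt each. Samples were grouped by the target, genotype and treatment in their labels, with 2 in every group except the single IgG sample. The labels do not say whether samples of a group came from separate mice.

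The authors deposited 1 merged peak list per target, in which the values are genomic coordinates, that is, another unit than counts or signal: the start and end of each peak in bp, with no score. The DDX55, RNA polymerase II and H3K9me3 lists are each named by 4 samples, 2 WT and 2 knockout, and the R-loop list by 8, of which 4 had RNase H; 3 samples (2 HA, 1 IgG) name none. Per the submitters' processing notes, the genome build was mm10 and the tools were fastp 0.12.4, Bowtie2 2.5.0, SAMtools 1.15.1, MACS3 3.0.0b1 and ChIPseeker 1.30.3. The notes used here give names only. Peak thresholds, the way samples were merged, whether peaks were called per sample or on pooled samples, any use of the spike-in DNA and any filter against controls were not given in the sources used here. The depth per sample is unknown, since the lists hold no counts. Signal per sample was not analysed here.

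Lists were compared on chromosomes 1 to 19, X and Y. Peaks on other sequences were only described. Genes came from a RefSeq gene table of GRCm38.p6, which has the coordinates of mm10 and holds 49993 genes, of which 21883 protein-coding genes on assembled chromosomes were used. The table gives no strand, exons or transcript starts, so the planned promoter window became a window of 3000 bp on each side of either gene end, called a gene end here, and the planned classes of untranslated region, exon and intron became gene body. A peak took its class from its midpoint, in the order gene end, protein-coding gene body, other annotated gene, intergenic.

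Overlap was at least 1 bp, computed with numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15 and checked with bedtools 2.31.1. Each overlap and annotation share was compared with 1000 random placements of the peaks within their chromosome, between its lowest and highest gene or peak coordinate, with a two-sided permutation p. The smallest p was 0.0020, and 0.0024 (overlap) or 0.00228 (annotation) after Benjamini-Hochberg adjustment. Assembly gaps inside chromosomes were not excluded, because no gap table was used here, and this lowers the random overlap. Shares have exact Clopper-Pearson 95% intervals from scipy 1.17.1. These cover counting error only, and peaks and genes are not replicates.

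Gene lists were tested at gene ends by two-sided Fisher exact tests against all other protein-coding genes, adjusted over 72 tests. H3K9me3 in gene bodies was tested with 100000 random draws of genes from the same 10 length classes. Genes with pairs of targets at their ends were compared by Fisher exact tests adjusted over 6 pairs. A threshold of 0.05 on adjusted p was used. The 18 gene lists, the tests, the named-genes rule and the alternatives were set before the data were examined, apart from those called added or chosen later. Added later were the gene-end definition, removal of places shared by H3K9me3 and RNA polymerase II, gene-body tests of R-loop and DDX55, shifts of the list in the gene-body test, the antigen receptor loci, counts in 1-Mb windows and all tests of explanations.

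The named-genes rule took Ddx55 itself; per list the 10 protein-coding genes, other than Gm-number and Rik clone symbols, whose gene ends met the widest peaks; up to 10 such genes with DDX55, R-loop and RNA polymerase II together; and up to 6 members per gene list and peak list, in alphabetical order, with a gene-end peak or, for H3K9me3, a gene-body peak. The gene-body part was also applied to R-loop and DDX55. Width stood in for score, which the lists lack. Any other gene named was chosen after its values were seen. The members of the naive T cell list without a gene-end peak are not reported here.

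On a simulated list of 240 peaks with 60 planted overlaps, 62 were counted where random placement gave 2.43. In another run 37 of 1000 unrelated lists, which held more peaks and had fewer placements each, had p under 0.05. That number of lists was raised after smaller runs of this check. Of 200 simulated gene lists with an effect 196 were called. Separately, 3 of 200 without one were called. The threshold behind each of these gene-list counts is not stated here, so they are not read as paired rates under one threshold. Nor are the simulated counts taken as error rates for clustered peaks, for rare peaks or for gene families that share peaks. Alternatives were other overlap rules, circular shifts, gene-end-matched placement, the wider 50% of each list, autosomes only, windows of 1000 bp, other gene backgrounds, no length matching and at least 5% of the gene body covered. Planned comparisons of genotype, RNase H and antibody specificity, and of base composition, G-quadruplex motifs and repeats, were not run, since values per sample and the genome sequence were not used here. Figures were drawn with matplotlib 3.10.9.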

Results

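CUT&Tag profiles were collected from CD4 naive T cells of the spleen and lymph nodes (labelled pLN) of wild-type (WT) mice and of mice lacking DDX55, a DEAD-box RNA helicase. In CUT&Tag an antibody guides a transposase to cut and tag the DNA near its target. The 23 samples comprised 4 H3K9me3, 4 RNA polymerase II and 4 DDX55 profiles, each with 2 WT and 2 knockout samples. They also comprised 8 profiles with the S9.6 antibody against DNA-RNA hybrids (R-loops), 4 per genotype, of which 4 were treated with RNase H. There were also 2 profiles of an HA tag and 1 IgG control, all labelled WT. H3K9me3 marks heterochromatin, and R-loops are structures in which RNA pairs with a DNA strand and displaces the other strand. The values were 4 merged peak lists, 1 per target, holding positions only, with no height, no score and no value per sample. The depth was therefore unknown. The labels of WT and knockout samples named the same list, and those of R-loop samples with and without RNase H did so too. Signal per sample, the HA profiles and the IgG profile were not analysed here, so no WT against knockout difference, no RNase H effect and no spread between replicates was measured.

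The DDX55 list was the smallest, with 243 peaks of median width 438 bp that covered 0.142 Mb. The R-loop list held 1499 peaks (median 528 bp, 1304 kb), the RNA polymerase II list 10924 (638 bp, 7.98 Mb) and the H3K9me3 list 16738 (611 bp, 13.8 Mb). On the assembled chromosomes 1 to 19, X and Y there were 215 DDX55, 1473 R-loop, 10898 RNA polymerase II and 16474 H3K9me3 peaks, and all comparisons used these. The gene knocked out in the mutant mice, Ddx55 (gene 67848, chromosome 5, 124552832 to 124569660, GRCm38), carried 1 RNA polymerase II peak of 686 bp at 124552927 to 124553612. No peak of the other 3 lists overlapped it.

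RNA polymerase II peaks lay at most of the fixed genes of T cell receptor signalling and naive identity. Of 30 fixed genes of T cell receptor signalling, 28 had a peak within 3000 bp of a gene end. Among them were Cd3d, Cd28 and Cd247, which encode a CD3 chain, a costimulatory receptor and the zeta chain. Such a peak need not overlap the gene. The peak taken for Cd28 (973 bp, from 60776032) lay outside its span, which ends at 60773359. The pair without such a peak, Lat and Thy1, is named here after the values were seen. Of 30 genes of naive identity and quiescence, 25 had a peak, among them the chemokine receptor gene Ccr7 with a 1423 bp peak and the antiproliferative genes Btg1 and Btg2 with peaks of 1978 and 2058 bp. Across the genome 33.5% of 21883 protein-coding genes (7331) had such a peak.

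Among activation and immediate-early genes, a peak lay within 3000 bp of an end of 26 of 39 members. These included the immediate-early genes Egr1 (910 bp) and Dusp2 (917 bp), the early activation marker Cd69 (1181 bp), Batf, Bcl6 and Ctla4. The peak taken for Ctla4 (303 bp, from 60917030) lay outside its span, which ends at 60915832. No peak lay at a gene end of 13 members, among them Ifng, Il2, Gzmb, Tbx21 and the immediate-early gene Nr4a2, which were picked out after the values were seen, and no part of the list was tested alone. The widest RNA polymerase II peaks at gene ends lay beside the splicing factor gene Tra2b (3468 bp), between Rsrp1 and Syf2 (3131 bp), beside Pnrc1 (3089 bp) and over the whole of Junb (3084 bp, chromosome 8, 84975908 to 84978991). The last peak was also within 3000 bp of Prdx2.

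Nearly all ribosomal protein and histone genes had an RNA polymerase II peak within 3000 bp of an end, inside the gene or beside it. Peaks lay at 74 of 80 ribosomal protein genes, such as Rpl12 with 1745 bp. They lay at 61 of 67 histone genes, such as H1f2 with 2116 bp. The histone list was picked by symbol pattern and is not limited to replication-dependent histones. They lay at 34 of 47 proteasome genes, 26 of 36 R-loop processing genes, among them Brca1 and the helicase gene Blm, and 19 of 29 genes of the H3K9 methylation machinery, among them Cbx3, Cbx5 and Atrx. Interferon and nucleic acid sensing genes had 21 of 37 and zinc finger protein genes 176 of 426. Olfactory receptor genes had 1 of 1106 (Olfr9), and vomeronasal receptor genes 1 of 353 (Vmn1r4).

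Genes of other blood cells had few RNA polymerase II peaks, but these short lists did not pass the test. A peak lay near 1 of 14 B cell genes (Cd79a), 2 of 20 myeloid genes (Cd68 and Fcgr3), 1 of 15 CD8 T and NK cell genes (Prf1) and 2 of 10 erythroid genes (Epor and Klf1). Adjusted Fisher p was 0.161, 0.115, 0.110 and 1 in that order. Imprinted genes had 5 of 29 (adjusted Fisher p = 0.227) and clustered protocadherin genes 21 of 57 (adjusted p = 1). The Pcdhga genes shared 1 peak of 877 bp near their common end. With windows of 1000 bp the gene lists below other genes rose from 2 to 4, and with shared places removed to 3. Some of the lists in this paragraph thus passed as lower under those settings.

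Each list was compared with the other protein-coding genes by a two-sided Fisher exact test, adjusted over 72 tests of 18 gene lists and 4 peak lists. The odds ratio for RNA polymerase II was 27.9 for T cell receptor signalling (95% interval 7.03 to 242, adjusted Fisher p = 1.16e-10) and 9.95 for naive identity (3.74 to 33.3, adjusted p = 2.41e-07). It was 3.98 for activation (adjusted Fisher p = 0.000155), 24.7 for ribosomal proteins (adjusted p = 2.78e-27), 20.3 for histones (adjusted p = 1.20e-21) and 5.21 for the proteasome (adjusted p = 5.08e-07). R-loop processing reached 5.18 (adjusted Fisher p = 1.78e-05), the H3K9 machinery 3.78 (adjusted p = 0.00294), interferon genes 2.61 (adjusted p = 0.0205) and zinc finger genes 1.41 (adjusted p = 0.00378). Olfactory receptors were at 0.00166 (adjusted Fisher p = 3.01e-198) and vomeronasal receptors at 0.00550 (adjusted p = 5.31e-60). With only the wider 50% of the peaks, the H3K9 machinery (1.63, adjusted Fisher p = 0.801), interferon genes (1.97, adjusted p = 0.274) and zinc finger genes (0.943, adjusted p = 1) no longer passed. In all 8 lists passed as higher there, against 10 in the main test, so a list that had not passed was gained. The odds ratio was then 6.28 for T cell receptor signalling, 13.6 for ribosomal proteins and 2.69 for the proteasome, and within 1000 bp of gene ends it was 9.67 for T cell receptor signalling, 15.3 for ribosomal proteins and 6.64 for naive identity. Neighbouring family members can share a peak, so p-values for clustered families, histones included, are too small.

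**Figure D1:**
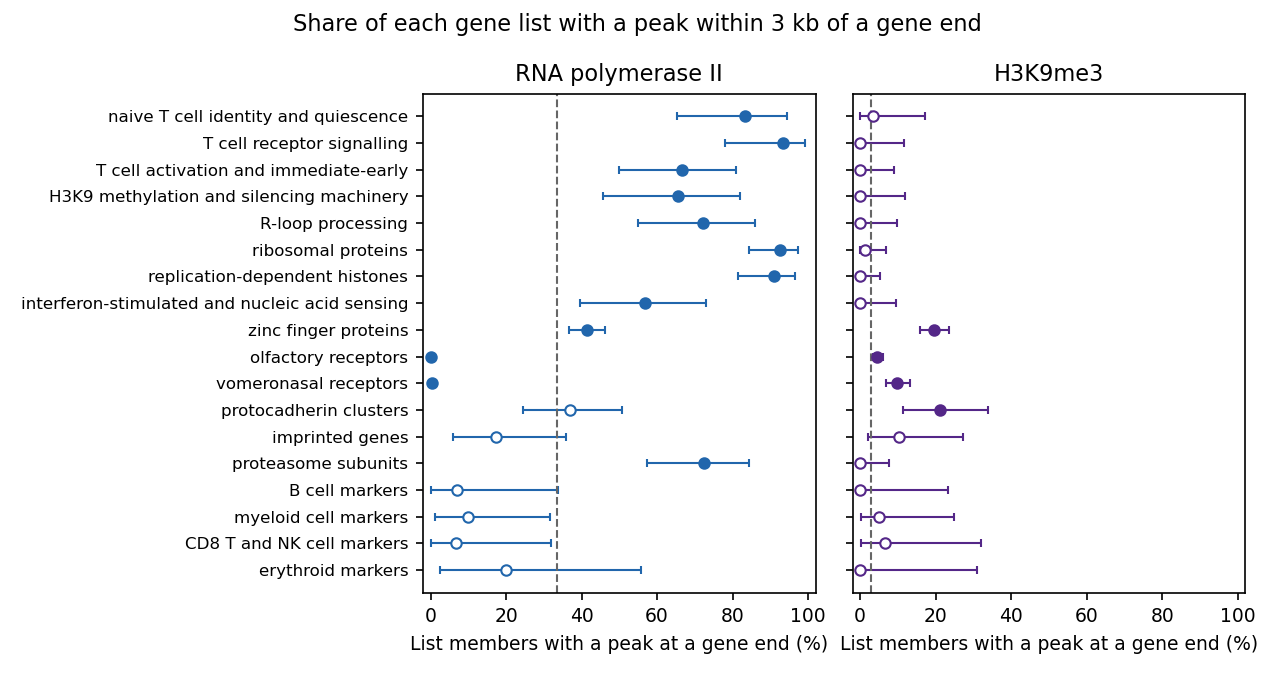
Percent of the members of each fixed gene list with a peak within 3000 bp of a gene end, for RNA polymerase II and H3K9me3, with bars for exact 95% intervals, filled markers for an adjusted p under 0.05 and a dashed line for the other protein-coding genes. RNA polymerase II peaks lay at 28 of 30 T cell receptor signalling genes and 1 of 1106 olfactory receptor genes.

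H3K9me3 peaks lay mostly away from genes, and a peak lay at a gene end of 648 protein-coding genes. Among the fixed lists, zinc finger protein genes had the most members marked in number, and clustered protocadherin genes the largest share (21.1% at gene ends and 36.8% in gene bodies, against 19.5% and 25.6%). Zinc finger protein genes had one at a gene end in 83 of 426 cases and in the gene body in 109 of 426. Zfp433 on chromosome 10 had a 4429 bp peak at its end, and the chromosome 4 cluster held Zfp988 (3988 bp), Zfp992 (3602 bp), Zfp991 (3572 bp) and Rex2, whose body carried 4436 bp. Clustered protocadherin genes had a gene-end peak in 12 of 57 cases, including Pcdha1 (862 bp) and Pcdhb10 (536 bp), and vomeronasal receptor genes in 34 of 353, including Vmn1r149 (1413 bp). The widest gene-end peak, 6957 bp, lay beside Duxf3 (gene 74399), a member of a repeated double homeobox family on chromosome 10.

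Olfactory receptor genes had an H3K9me3 gene-end peak in 50 of 1106 cases, such as Olfr1109 with 1350 bp. Of the imprinted genes, Impact, Magel2 and Ndn had gene-end peaks (3 of 29, adjusted Fisher p = 0.175), and Snrpn and Usp29 had peaks inside the gene. Genes of T cell receptor signalling, activation, the H3K9 machinery, R-loop processing, interferon sensing, histones and the proteasome had 0 gene-end peaks. So did the 14 B cell and 10 erythroid genes, and of the naive list Slfn2 had 1 (1407 bp). None of these lists passed as lower (lowest adjusted Fisher p = 0.694), and lists of this size could not do so even with 0 peaks. Rpl10l was the ribosomal protein gene with a peak (625 bp), and Klrb1c (1510 bp) and Fcgr3 (1964 bp) were the other marker genes with one. The windows with most peaks were on chromosome 4 from 147000001 to 148000000 (95 peaks) and on chromosome 12 from 22000001 to 23000000 (94 peaks).

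By midpoint 71.3% of H3K9me3 peaks were intergenic, against 50.4% under random placement within chromosomes, and 3.97% lay within 3000 bp of a gene end against 7.84%, 0.506 times the random share. For RNA polymerase II 61.1% lay at gene ends against 8.60% at random (7.10-fold), and 10.1% were intergenic against 47.7%. Permutation p was 0.0020 for each of these shares, the smallest that 1000 placements could give, and 0.00228 after adjustment. Within 1000 bp of gene ends RNA polymerase II was 15.6-fold over random. In Fisher tests on gene ends the odds ratio for H3K9me3 was 8.95 for zinc finger genes (95% interval 6.85 to 11.6, adjusted p = 1.70e-42), 8.88 for protocadherins (4.26 to 17.2, adjusted p = 6.18e-07), 3.63 for vomeronasal receptors (adjusted p = 1.85e-08) and 1.60 for olfactory receptors (adjusted p = 0.0162). Within 1000 bp of a gene end zinc finger genes passed at 7.80 (adjusted Fisher p = 3.90e-20), while protocadherins (3.65, adjusted p = 0.197), vomeronasal receptors (2.14, adjusted p = 0.0931) and olfactory receptors (0.830, adjusted p = 1) did not. With the wider 50% of peaks, olfactory receptors were at 0.893 (adjusted Fisher p = 1).

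In gene bodies, against genes of like length, H3K9me3 was 5.63-fold over the random mean for zinc finger genes, 4.08-fold for vomeronasal receptors and 3.10-fold for protocadherins, each with adjusted permutation p = 0.00012. Of the 21 marked protocadherins, 12 were Pcdha genes with overlapping spans that shared the same peak. Vomeronasal receptors were at 1.81-fold without length matching and did not pass when 5% of the gene had to be covered (2.03-fold, adjusted permutation p = 0.231), where zinc finger genes were at 9.69-fold and protocadherins at 11.9-fold. Without length matching protocadherins were at 6.94-fold. When, in a test added later, the peaks were shifted as a whole along the chromosomes, zinc finger genes remained above at 2.17-fold (adjusted permutation p = 0.0360), while vomeronasal receptors (1.65-fold, adjusted p = 0.1998) and protocadherins (1.98-fold, adjusted p = 0.696) did not pass. The naive T cell list, with 0 of 30 gene bodies marked, was not below genes of like length (2.30 expected, adjusted permutation p = 0.573) and lay below only the shifted mean of 5.34 (adjusted p = 0.0360), where H3K9me3 peaks in general also lay in gene bodies less than at random. Reads of near-identical cluster members can be assigned to the wrong copy, so the exact member marked is uncertain for the Zfp, Vmn, Speer and Duxf3 families.

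**Figure D2:**
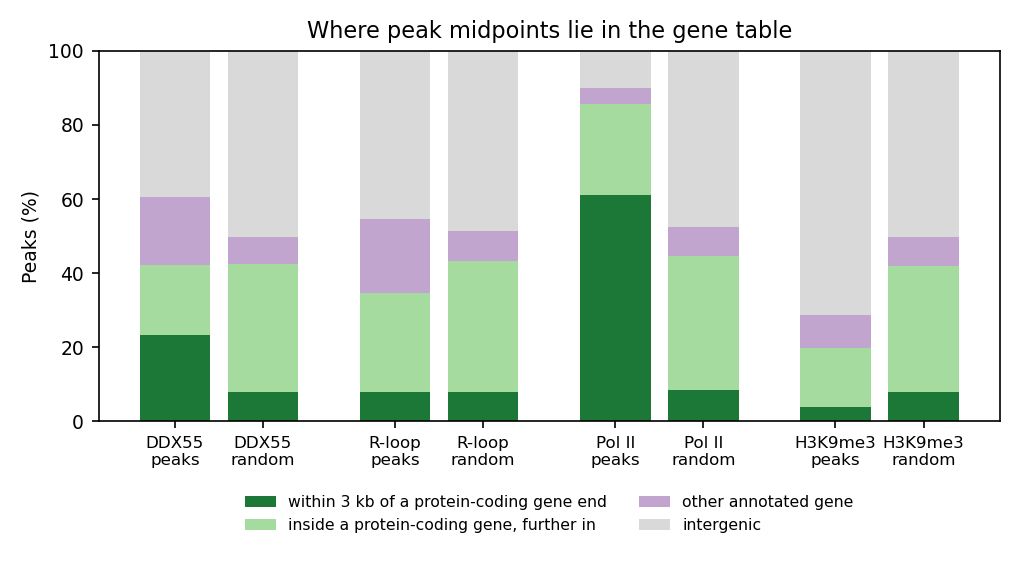
Percent of peak midpoints in each annotation class for the 4 lists, beside the mean of 1000 random placements within chromosomes. RNA polymerase II stands out at gene ends (61.1%) and H3K9me3 in intergenic DNA (71.3%).

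R-loop peaks lay in 754 of 2714 windows of 1 Mb, and the window with most of them lay in the immunoglobulin heavy chain locus. Igh held 97 of the 1473 peaks, the widest 10106 bp long at chromosome 12, 115219862 to 115229967. Another 21 lay in the T cell receptor alpha locus Tcra, with a widest of 8256 bp, and 3 in Igk. Tcrb, Tcrg and Igl held 0. A further 32 lay in Dnm3, a dynamin gene on chromosome 1, where they covered 62941 bp and no peak of the other lists was present.

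The 1-Mb window with most R-loop peaks, on chromosome 12 from 115000001, held 89, and the next, on chromosome 18 from 81000001, held 53 in a stretch with 0 protein-coding genes. A window on chromosome 7 from 140000001 held 25, among olfactory receptor genes such as Olfr539 (2248 bp) and Olfr525 (1895 bp). The widest R-loop peak at a gene end covered 8535 bp of Cd4 (gene 12504), the coreceptor gene of these cells, at chromosome 6, 124879678 to 124888212. The next were over Dbh (8007 bp), which encodes dopamine beta-hydroxylase, the integrin gene Itgax (4255 bp), Gfra1 (3439 bp) and Sardh (2866 bp). The Dbh and Sardh peaks lay in one window of chromosome 2 from 27000001, with the peak shared by Adamtsl2 and Fam163b (2664 bp).

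R-loop peaks did not gather at the ends of protein-coding genes. By midpoint 7.88% lay there (95% interval 6.55 to 9.37) against 7.98% at random (adjusted permutation p = 0.929), although within 1000 bp of gene ends the share was 1.36 times random (adjusted p = 0.0220). Genes of other classes, which include the whole antigen receptor loci, held 20.1% against 8.11% (adjusted permutation p = 0.00228). The R-loop peaks of those loci may make up much of this excess, which was not tested without them. No gene list passed at gene ends. Imprinted genes, with Impact (1185 bp) and Rtl1 (473 bp), came closest at 2 of 29 (odds ratio 11.8, adjusted Fisher p = 0.0607), and zinc finger genes had 4 of 426, Zfp143, Zfp697, Zfp747 and Zfp788 (adjusted p = 0.863). In gene bodies no list passed either, and the myeloid genes Itgam and Itgax were 2 of 20 (11.1-fold, adjusted permutation p = 0.238). The 6 antigen receptor loci, looked at because R-loop peaks had been seen there, held 121 peaks, and no test of the R-loop list there is given for that reason. The 10 fullest windows held 22.2% of the peaks against 2.91% at random (permutation p = 0.0020), while the 10 fullest for DDX55 held 39.5% against 9.39%. Because RNase H-treated samples named the same list, an R-loop peak here is a place where S9.6 signal was called and is not known to be RNase H-sensitive.

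**Figure D3:**
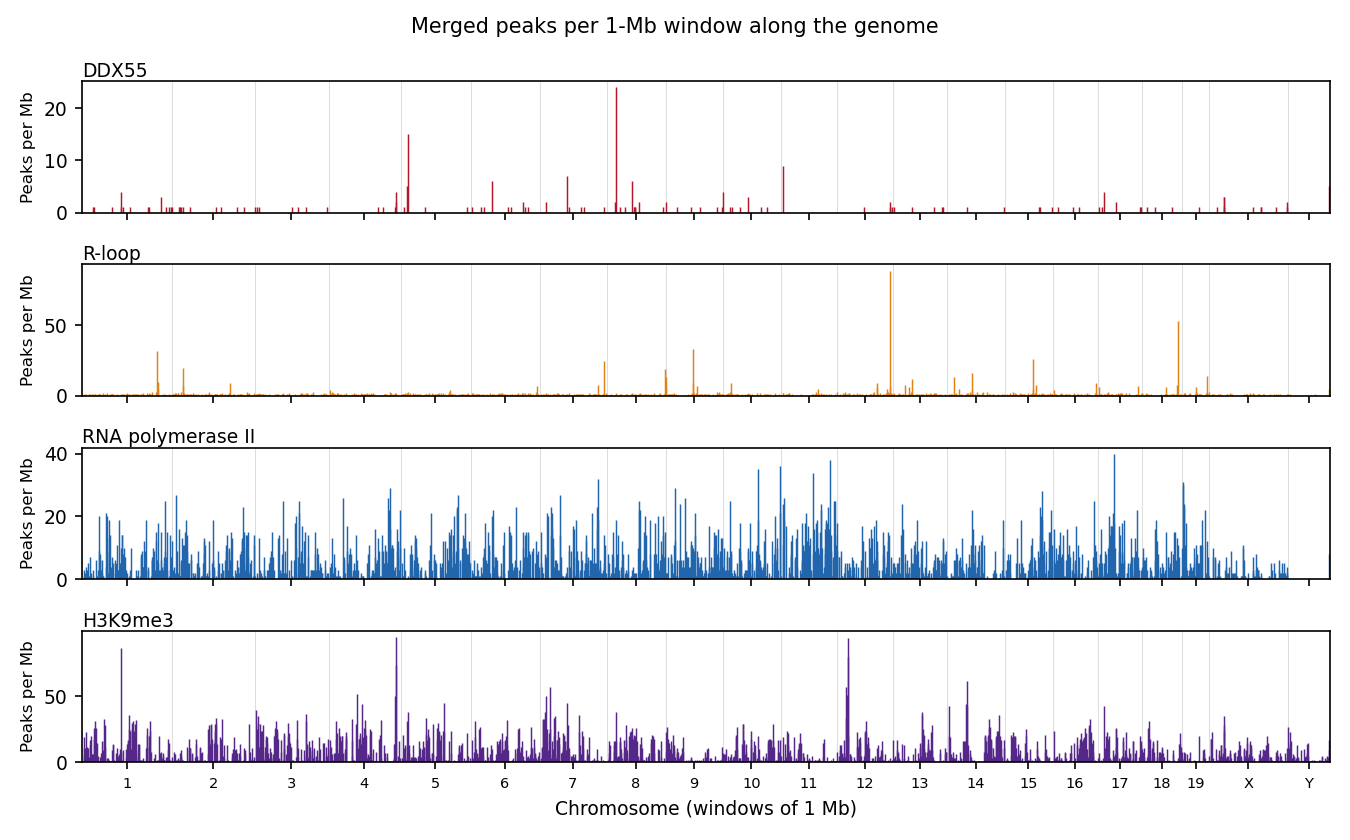
Number of merged peaks in each of 2714 windows of 1 Mb along the assembled chromosomes, one panel per list. The highest counts were 89 for R-loop on chromosome 12, 24 for DDX55 on chromosome 8, 40 for RNA polymerase II and 95 for H3K9me3.

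**Figure D4:**
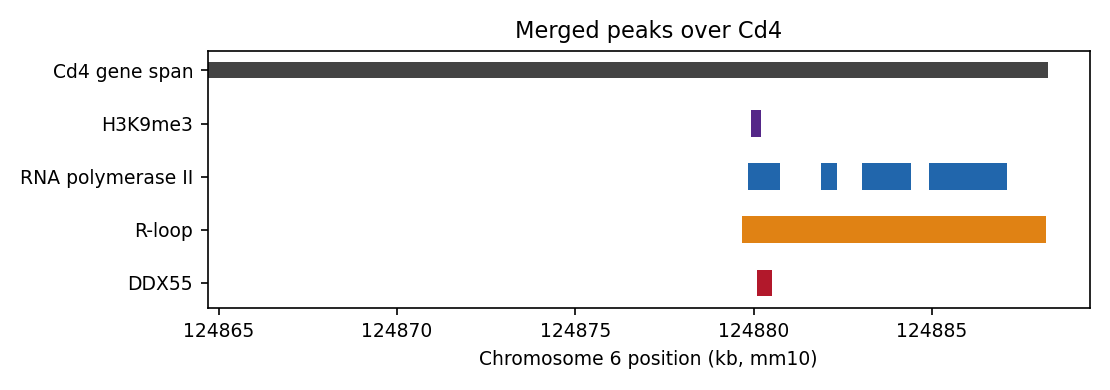
Peaks of the 4 lists along Cd4 on chromosome 6, with position in kb on the horizontal axis and each bar spanning a merged peak. The R-loop peak spans 8535 bp, and the DDX55 (440 bp) and H3K9me3 (287 bp) peaks lie inside it, as do 4 RNA polymerase II peaks.

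DDX55 peaks often met H3K9me3 and RNA polymerase II peaks. Of 215 peaks, 142 (66.0%, 95% exact interval 59.3 to 72.3) shared at least 1 bp with an H3K9me3 peak and 91 (42.3%, 35.6 to 49.2) with an RNA polymerase II peak, while 24 (11.2%, 7.28 to 16.2) met an R-loop peak. A window on chromosome 8 from 20000001 held 24 DDX55 peaks, a window on chromosome 5 from 15000001, with Speer4c, held 15, and a window on chromosome 11 from 3000001 held 9, of which 8 lay in Sfi1, a gene for a centrosomal protein. The long noncoding RNA gene Snhg14 held 7. The Duxf3 gene had peaks of all 4 lists at its ends, with 1379 bp for DDX55, 1337 bp for R-loop and 988 bp for RNA polymerase II.

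Other genes with wide DDX55 peaks at an end were AY761185 on chromosome 8 (1209 bp), the Fc receptor gene Fcgr3 (854 bp), Eppk1 (666 bp), Apool and the chloride channel gene Clcn3 (542 bp each). Cbx5, which encodes the heterochromatin protein HP1 alpha, had a DDX55 peak of 288 bp at chromosome 15, 103240024 to 103240311, inside a 1646 bp RNA polymerase II peak. Inside the gene body, DDX55 peaks lay in the zinc finger genes Zfp600 (605 bp), Zfp978 (468 bp), Zfp992 (351 bp) and Zfp704 (318 bp), and in Cd4 (440 bp). The 18S ribosomal RNA pseudogene Rn18s-rs5 on chromosome 17 overlapped a peak of each list, from 3967 bp for RNA polymerase II to 5753 bp for R-loop.

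All these DDX55 overlaps exceeded random placement, with 1.77 peaks expected on H3K9me3 (80.5-fold), 1.08 on RNA polymerase II (84.3-fold) and 0.137 on R-loops (175-fold). Permutation p was 0.0020 for each, the smallest that 1000 placements could give, and 0.0024 after adjustment over 12 ordered pairs. By midpoint 23.3% of DDX55 peaks lay at gene ends against 8.02% (2.90-fold, adjusted permutation p = 0.00228; 4.83-fold within 1000 bp). No gene list passed for DDX55, at gene ends or in gene bodies. Only 56 of 21883 protein-coding genes had a DDX55 gene-end peak, so no list could have passed as lower there and short lists had little power. Cbx5 and Fcgr3 were the members with gene-end peaks (adjusted Fisher p = 0.224 and 0.171 for their lists), and zinc finger gene bodies reached 3.66-fold (adjusted permutation p = 0.820). Outside places where H3K9me3 and RNA polymerase II peaks overlap, 105 DDX55 peaks were left, of which 46 met H3K9me3 (43.8%, 56.2-fold), 23 met RNA polymerase II (21.9%, 51.1-fold) and 3 met R-loops (2.86%, 51.7-fold). The list joins WT and knockout samples, so a DDX55 peak is not known to depend on DDX55.

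Among the other targets, R-loop peaks met H3K9me3 peaks more often than RNA polymerase II peaks. Of 1473 R-loop peaks, 271 (18.4%, 95% interval 16.4 to 20.5) met an H3K9me3 peak, 18.3-fold over random, and 51 (3.46%) met RNA polymerase II, 5.33-fold, each with adjusted permutation p = 0.0024. RNA polymerase II and H3K9me3 shared places about as often as random placement gave, with 97 of 10898 RNA polymerase II peaks against 99.9 (adjusted permutation p = 0.795) and 92 of 16474 H3K9me3 peaks against 99.4 (adjusted p = 0.512). Counting peaks within 1000 bp of each other, the first ratio was 0.506 (adjusted permutation p = 0.0020). It was 1.36 when at least 50% of the shorter peak had to be shared (adjusted permutation p = 0.0109) and 1.3 when placements kept gene-end peaks at gene ends (adjusted p = 0.00872), so its direction depended on the definition.

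**Figure D5:**
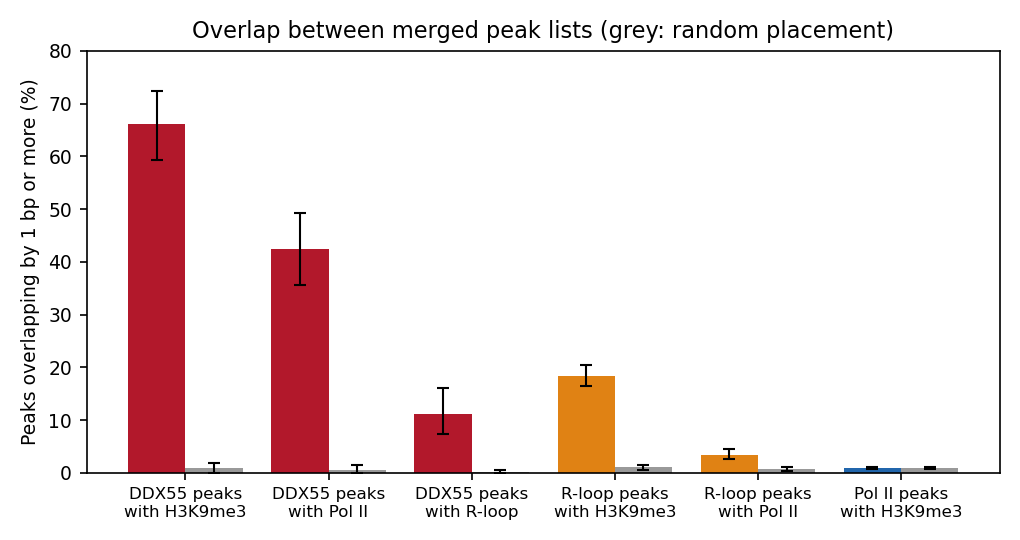
Percent of the peaks of a list that share at least 1 bp with another list for 6 pairs, observed (coloured, bars for exact 95% intervals) and under random placement (grey, bars for the middle 95% of placements). DDX55 peaks met H3K9me3 in 66.0% and RNA polymerase II in 42.3% of cases.

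At the level of genes, DDX55 and H3K9me3 shared 25 genes, while RNA polymerase II and H3K9me3 shared fewer than expected. Of 56 protein-coding genes with DDX55 at an end, 42 also had RNA polymerase II there (odds ratio 5.98, 95% interval 3.20 to 11.9, adjusted Fisher p = 7.20e-10), and the 25 with H3K9me3 gave an odds ratio of 27.4 (15.4 to 48.3, adjusted p = 3.79e-23). R-loops joined DDX55 at 6 genes (19.7, adjusted Fisher p = 1.70e-06) and H3K9me3 at 17 of 138 genes (4.70, adjusted p = 1.08e-06). RNA polymerase II and H3K9me3 met at 105 genes, where 217 would be expected (odds ratio 0.375, adjusted Fisher p = 3.79e-23). R-loops and RNA polymerase II met at 52 genes against 46.2 expected (1.2, adjusted Fisher p = 0.320), but at 1.99 with windows of 1000 bp (adjusted p = 0.00231). The 5 genes with DDX55, R-loop and RNA polymerase II at an end all had H3K9me3 as well, and Duxf3 was the one with an established symbol. With the wider 50% of each list the odds ratio was 84.4 for DDX55 with R-loops, 82.6 for DDX55 with H3K9me3 and 3.63 for DDX55 with RNA polymerase II, and with windows of 1000 bp it was 7.21 for R-loops with H3K9me3. Fisher exact tests were adjusted over 6 pairs, and genes are not independent replicates.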

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

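The test of DDX55 and H3K9me3 inside the Cd4 peak was chosen only after the result was seen, as was removal of shared places; every pattern weighed here was itself noticed in these data. Peaks on unplaced or unlocalised sequences were used in no test. They numbered 26 for DDX55, 26 for R-loop, 24 for RNA polymerase II and 262 for H3K9me3 (10.7%, 1.73%, 0.220% and 1.57% of each list). On 1 unplaced sequence the counts were 15, 15, 15 and 20 in the same order.

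DDX55 peaks lay on H3K9me3 peaks 80.5-fold more often than at random. Repeated or poorly assembled sequence that collects reads with any antibody was tested by leaving out some peaks. These lay within 100000 bp of places shared by H3K9me3 and RNA polymerase II. The places made 57 regions of 12.9 Mb, and only 105 of 215 DDX55 peaks lay outside them. Of the 105, 43.8% met H3K9me3, against 66.0% of all, still 56.2-fold over the 0.819 expected. This argues against such shared places as the whole cause, although they held a large part of the overlap. A small number of crowded windows was tested with DDX55 peaks that had no other DDX55 peak within 1 Mb. Of 85 such isolated peaks, 65 lay outside those shared places. Among the 65, 16 (24.6%) met H3K9me3, against 66.0% of all DDX55 peaks, 32.3-fold over the 0.495 expected. This argues against crowding as the whole cause, although crowded or shared places held a large part of the overlap. With so few expected, the fold alone says little about the size of that part. Multicopy windows without RNA polymerase II and dispersed repeats stay open, since no sequence was used here, and so does unspecific antibody signal. Binding of DDX55 itself was not tested, because the list joins WT and knockout samples.

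R-loop peaks crowded into 10 windows that held 327 of 1473. Extra DNA copies could raise the other lists there as well. Their peaks were 0.483 times the mean of random sets of 10 windows (49 against 101). RNA polymerase II was at 1.03 times and H3K9me3 at 0.0994 times. DDX55, with 2 peaks against 0.762, was at 2.62 times (permutation p = 0.270). The low pooled ratio came from H3K9me3 (6 against 60.4), and peak numbers also depend on where each target lies. This test therefore cannot decide on extra copies. The reading rule of this test was corrected after its value was seen, to match the bound written earlier, and the labels do not say that the libraries came from the same mice, so copies private to the R-loop samples stay open. Transcription was tested by nearness to RNA polymerase II. Of these R-loop peaks 3.36% (95% interval 1.69 to 5.94) lay within 10000 bp of such a peak, against 8.73% elsewhere (Fisher exact p = 0.000783). The peaks come from only 10 windows and are not independent, so the interval is too narrow and the p too small. The low share itself argues only against called RNA polymerase II peaks nearby as the cause. Transcription without a called peak stays open, since the depth is unknown and RNA polymerase II peaks lay mostly at gene ends. No biological explanation by genotype was tested.

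The widest R-loop peak at a gene end lay on Cd4. Transcription of an active T cell gene predicts R-loop peaks in its peers, but 0% of 27 other T cell receptor signalling genes with RNA polymerase II had one in the gene body (95% interval 0 to 12.8). That upper limit is above the 10% written beforehand as evidence against this cause but below the 50% it needs. Extra copies of a Cd4 fragment in the cells cannot be told apart from other causes. The 2 peaks of DDX55 and H3K9me3 in the interval had been seen before this test was chosen, and R-loop peaks meet both lists above random anyway. Of 29 other genes of the list, 0 had a DDX55 or H3K9me3 peak in the gene body. Among genes of like length the share was only 7.25% for H3K9me3 and 0.422% for DDX55, so few were expected whatever the cause. A true R-loop at Cd4 stays open.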

How the results depend on the processing

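Removal of places shared by H3K9me3 and RNA polymerase II, and shifted lists in the gene-body test, were chosen after seeing the data. All DDX55 and R-loop overlaps stayed above random under every alternative run, but their size moved: DDX55 with R-loop from 51.7-fold (3 peaks, shared places removed) to 421-fold (wider 50%), DDX55 with H3K9me3 from 32.6-fold (within 1000 bp) to 123-fold (wider 50%), DDX55 with RNA polymerase II from 34.0-fold (within 1000 bp) to 123-fold (50% shared), R-loop with H3K9me3 from 8.79-fold (within 1000 bp) to 25.5-fold (50% shared), and R-loop with RNA polymerase II from 2.99-fold (within 1000 bp) to 6.26-fold (50% shared). RNA polymerase II against H3K9me3, and H3K9me3 against RNA polymerase II, were not beyond random in the main analysis (0.971 and 0.926 times), but were above it at 1.36 and 1.29 times with at least 50% of the shorter peak shared and at 1.3 and 1.26 times with gene-end-matched placement, and below it at 0.506 and 0.482 times within 1000 bp; the cause was not tested. With windows of 1000 bp, R-loop peaks at gene ends rose from 0.987 to 1.36 times random, the R-loop and RNA polymerase II odds ratio passed at 1.99, gene lists below other genes for RNA polymerase II went from 2 to 4, gene lists above for H3K9me3 from 4 to 1, and olfactory receptors for H3K9me3 to an odds ratio of 0.830; a smaller window changes the genes counted, and no further cause was tested. With the wider 50% of each list, olfactory receptors for H3K9me3 (0.893) and zinc finger genes for RNA polymerase II (0.943) fell below 1, with fewer peaks tested. In gene bodies, no length matching put 1 list below expectation (olfactory receptors) against 0, and circular shift left 1 list above against 3 and put 1 below against 0. No paired analysis was possible because the merged lists hold no value per sample, and for the same reason replicates could not be left out. Also not run were 1 start per gene, all sequence properties and their alternatives, and every genotype alternative. Unknown depth limits the absence of a peak, which is not absence of the target.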

Other observations

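The tests in this part were chosen after the data were seen. Antigen receptor loci also held peaks of the other lists. RNA polymerase II had 13 peaks in Tcra, the widest 1000 bp, 8 in Tcrb, the widest 1493 bp, 2 in Igh and 0 in Igk, Igl and Tcrg. H3K9me3 had 53 peaks in Igk, the widest 3841 bp, 5 in Igh, 2 in Tcra and 0 in Tcrb. Over the 6 loci neither H3K9me3 (60 peaks against 60.1 at random, permutation p = 1) nor RNA polymerase II (23 against 31.5, p = 0.160) departed from random placement, and the 3 DDX55 peaks, all in Igh, passed against random placement (p = 0.0260) but not against shifted lists (p = 0.132). The difference between the loci was not tested.

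The imprinted region of chromosome 7 carried H3K9me3 peaks. Snhg14, the long noncoding transcript that spans Snrpn, held 50 H3K9me3 peaks, the widest 6001 bp, with 7 DDX55, 3 RNA polymerase II and 1 R-loop peak. Sfi1 on chromosome 11 held 13 H3K9me3, 8 RNA polymerase II, 8 DDX55 and 2 R-loop peaks. Impact, another imprinted gene, had an R-loop peak of 1185 bp, an H3K9me3 peak of 693 bp and an RNA polymerase II peak of 375 bp at an end.

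By combination over all sequences, 92 of the 243 DDX55 peaks met H3K9me3 alone, 49 met H3K9me3 and RNA polymerase II, 33 met RNA polymerase II alone and 24 met all 3 other lists. R-loops alone met 2, R-loops with H3K9me3 met 3, and 40 met no other peak. Of the 65 isolated DDX55 peaks outside places shared by H3K9me3 and RNA polymerase II, 21 met RNA polymerase II, 78.9-fold over random (permutation p = 0.0020, the smallest possible). The mitochondrial genome held 2 peaks in each of the DDX55, RNA polymerase II and H3K9me3 lists and 0 in the R-loop list. They lay at nearly the same places: 123 to 6546 and 10911 to 16101 for DDX55, and 145 to 6579 and 10863 to 16033 for RNA polymerase II. For H3K9me3 they were 123 to 6544 and 10924 to 16171. Unspecific signal would give such shared places, and this was not tested further.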
